A study of Homo sapiens with 16 samples.

How the data were processed

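RNA was measured by sequencing in 16 libraries of HCT116 cells, 4 for each combination of control or TRIM28 siRNA with lactate or solvent, and groups were taken from the sample labels. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Per the submitters' processing notes, reads were aligned to GRCh38 with HISAT2 and tested with DESeq2, with no version given for either; the counting tool, its annotation and its strand setting are not stated. The authors deposited a table of whole-number read counts for 60624 Ensembl genes. A second deposited table holds FPKM values for 42694 of these genes. Over 11120 genes compared, all ratios of these FPKM to the counts lay within 0.1% of a single factor per library. The authors also deposited, for lactate against solvent in each siRNA background, a log2 fold change, an unadjusted p-value and an adjusted p-value per gene, and a short sheet of 89 selected genes with their counts. How that selection was made is not stated. Gene names and positions are those of the deposited tables. Of 41206 genes that GENCODE release 29 also holds, 99.8% overlap its position for the same identifier.

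Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 17649, with a median count of 239 per library. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, with 12 residual degrees of freedom. The common dispersion of 0.00175 corresponds to a coefficient of variation of 4.19% between replicates. Pairs of replicates differed by 2.08 to 3.91 times the chi-square per degree of freedom of counting noise, so none of them agreed within sampling noise alone. The 5 comparisons were TRIM28 siRNA against control siRNA in solvent and in lactate, lactate against solvent with each siRNA, and the interaction, which is the lactate effect with TRIM28 siRNA minus that with control siRNA. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and each adjusted p for a gene is edgeR's unless DESeq2 or limma is named. Fold changes are on the log2 scale with their standard error (SE). Levels are CPM, which are read counts scaled to 1e6 per library with the TMM factors, as mean and SD over 4 libraries.

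In addition, 31 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Over the 5 comparisons 57 lists passed. With the correlation estimated for each list 15 of the 57 still passed, and with fry, which tests each list on its own, 38 did. The estimated value is printed beside each list. Correlations of effects across genes compare pairs of contrasts that share no library. Overlaps of calls are set against the number for independent lists.

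The rule for which genes are named was fixed at the same time. It took TRIM28, the 10 largest rises and the 10 largest falls of each comparison among genes with an adjusted p under 0.05, a mean CPM of at least 1 and, except for the interaction, no overlap between the libraries of the groups. It further took up to 4 members of each gene list that passed camera or held at least 3 called members, those with the smallest adjusted p, and the 10 genes of the short sheet with the smallest interaction p. Not all genes it allows are named, and the values of some are not reported here. Reads of near-identical copies and of overlapping genes cannot be told apart in these counts, and such genes are reported as uncertain.

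The fit was tested on simulated data. Counts for the real genes were drawn with the real library sizes and spread, 200 genes were changed by a known fold in 1 group, and about as many genes as in the real data passed the filter. With a fold of 1.5, edgeR recovered 69.5% of the changed genes among 17298 for lactate with control siRNA, 67.5% among 17291 for lactate with TRIM28 siRNA, 60.5% among 17299 for the interaction, 71.5% among 17313 for TRIM28 siRNA in solvent and 66.5% among 17295 in lactate. With a fold of 2 these values were 78%, 85.5%, 76.5%, 84% and 85%, among 17318, 17303, 17299, 17306 and 17293 genes. With a change of 0.32 on the log2 scale they were 52%, 58%, 23.5%, 47.5% and 56%, among 17278, 17300, 17294, 17298 and 17301 genes. With 0.20 they were 23%, 27%, 9%, 25.5% and 28%, among 17293, 17307, 17315, 17296 and 17297 genes. Wrong calls numbered 1 to 14 in a simulation. These values hold for 200 changed genes, the real total counts of 13610341 to 16006696 per library and 4 libraries per group. Most changes of 0.20 would be missed there. With TRIM28 siRNA 9591 genes were called in solvent and 9479 in lactate, and so many calls ease the adjusted threshold. Called changes there went down to 0.08 on the log2 scale, so the simulated recovery does not carry over to the TRIM28 siRNA comparisons.

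Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, a stricter filter (CPM of at least 1 in at least 4 libraries), the replicate number as a block, a fit on the 8 libraries of a comparison alone, limma on log2 of the deposited FPKM plus 1, a minimum absolute log2 fold change of 1, leaving out each library in turn and, added later, leaving out pairs of control siRNA lactate libraries. The replicate numbers were checked and not taken as pairs. Sequences of 7 bases in 3′ UTRs of GENCODE release 29 were tested for lower or higher ranks of fold change, over 12761 genes with a 3′ UTR of at least 30 bases and a mean CPM of at least 1 and 15969 sequences found in at least 100 genes. A sequence planted in simulated data was recovered in 10 of 10 runs. The sequence was then picked in a random 6380 of these genes and tested in the other 6381. List scores are the mean log2(CPM + 1) of the members, and their interaction was tested over all 4900 reassignments of the lactate labels within each siRNA, against the largest t over the 31 lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and permutation tests, and matplotlib 3.10.9 for figures. Reads were not analysed here, and neither were repeat elements, which gene counts do not cover.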

Results

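The data were RNA sequencing read counts from HCT116 cells, a human colorectal carcinoma line. Cells received a control siRNA or an siRNA against TRIM28 at 10 nM and, 24 h later, sodium lactate at 10 mM or its solvent for another 24 h. The 4 groups held 4 libraries each, 16 in all. Total counts per library ran from 13610341 to 16006696. The mean was 14.3 ± 0.343 (SD, n = 4, in units of 1e6 counts) with control siRNA and solvent, 14.7 ± 1.14 with control siRNA and lactate, 15.6 ± 0.379 with TRIM28 siRNA and solvent and 15.4 ± 0.196 with TRIM28 siRNA and lactate. TRIM28 is a corepressor that KRAB zinc finger proteins bring to chromatin. The question set for these libraries was whether lactate acts on gene expression in a way that needs TRIM28.

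TRIM28 itself (ENSG00000130726, chromosome 19, 58544064 to 58550722 on GRCh38) stood at 537 ± 26.8 CPM (normalised read counts, scaled to 1e6 per library) with control siRNA and solvent (SD, n = 4) and at 545 ± 22.6 with control siRNA and lactate. With TRIM28 siRNA it fell to 72.9 ± 1.43 CPM in solvent, 13.6% of control, and to 78.2 ± 2.51 CPM in lactate, 14.4% of control. All 8 libraries labelled TRIM28 siRNA lay between 72.0 and 81.8 CPM, and the 8 labelled control siRNA between 515 and 572 CPM. The log2 fold change was −2.88 ± 0.04 (SE, edgeR adjusted p = 3.07e-57) in solvent and −2.80 ± 0.04 (edgeR adjusted p = 1.21e-56) in lactate. Lactate was followed by no detectable change of TRIM28 with control siRNA (log2 fold change 0.02 ± 0.04, edgeR adjusted p = 0.882) or with TRIM28 siRNA (0.10 ± 0.04, edgeR adjusted p = 0.227).

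**Figure D1:**
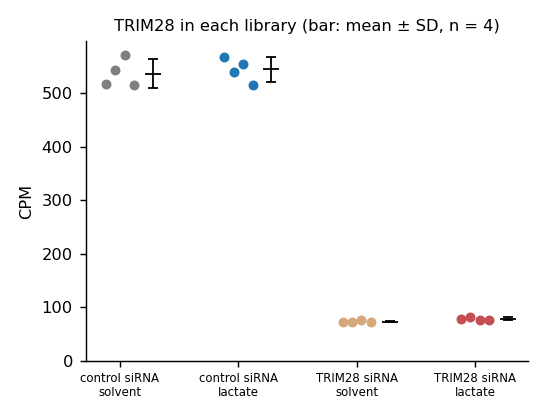
TRIM28 in CPM (normalised read count, vertical axis) in each of the 16 libraries, by group, with the group mean and SD (n = 4) as a bar beside the points. The 8 TRIM28 siRNA libraries lie between 72.0 and 81.8 CPM and the 8 control siRNA libraries between 515 and 572 CPM.

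The first comparison asked what TRIM28 siRNA changed in solvent. Of 40 targets of the p53 transcription factor 28 rose and 4 fell, while 34 of 36 mitotic and 44 of 47 DNA replication genes fell. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687337), which encodes the cell cycle inhibitor p21, rose from 304 ± 11.1 to 1087 ± 19.4 CPM (SD, n = 4 each), a log2 fold change of 1.84 ± 0.04 (SE). GDF15, a secreted stress cytokine, rose from 101 ± 5.55 to 329.9 ± 9.74 CPM, and MKI67, which encodes the proliferation antigen Ki-67, fell from 715 ± 33.2 to 344 ± 20.2 CPM. Of 17649 genes tested, 9591 changed, 4809 upward and 4782 downward, with a median absolute log2 fold change of 0.42, and 1042 of them changed by at least 1 on the log2 scale.

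Among p53 targets 28 of 40 tested members rose and 4 fell, and the counts were the same adjusted over the list alone (camera adjusted p = 1.25e-10, adjusted p = 0.00155 with an estimated correlation). PLK3, a stress-activated kinase, rose by 1.61 ± 0.05 on the log2 scale (SE), and BBC3, which encodes the proapoptotic protein PUMA, by 1.37 ± 0.05. Of 36 mitotic genes 34 fell, the same number adjusted over the list alone, and none rose (camera adjusted p = 1.03e-26, adjusted p = 0.00206 with an estimated correlation). CENPF, a kinetochore protein, changed by −1.03 ± 0.04, ASPM, a spindle pole protein, by −1.16 ± 0.05, and BIRC5, the chromosomal passenger protein survivin, by −1.21 ± 0.05. Of 47 DNA replication genes 44 fell and 1 rose, or 45 and 1 adjusted over the list alone. That call (camera adjusted p = 1.80e-17) was lost with adjusted p = 0.0948 with an estimated correlation. The replicative helicase subunits MCM7, MCM3 and MCM4 changed by −0.89 ± 0.04, −1.18 ± 0.05 and −1.04 ± 0.06.

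Lipid synthesis genes fell with TRIM28 siRNA in solvent. Of 17 fatty acid synthesis genes 14 fell and 2 rose, in the same numbers adjusted over the list alone (camera adjusted p = 1.30e-07, adjusted p = 0.00155 with an estimated correlation). The stearoyl-CoA desaturase SCD fell from 2252 ± 69.0 to 846 ± 21.9 CPM and fatty acid synthase, FASN, from 2776 ± 78.1 to 1509 ± 24.6 CPM (SD, n = 4 each). The acetyl-CoA carboxylase ACACA changed by −0.78 ± 0.04, and ELOVL1, an elongase of very long fatty acids, went the other way, from 90.1 ± 6.90 to 211 ± 10.2 CPM. Of 26 cholesterol synthesis genes 20 fell and 2 rose, again in the same numbers adjusted over the list alone (camera adjusted p = 4.18e-08, adjusted p = 0.0948 with an estimated correlation). The sterol reductase TM7SF2 changed by −1.15 ± 0.06, the squalene synthase FDFT1 by −0.79 ± 0.04 and the squalene epoxidase SQLE by −0.74 ± 0.04.

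Hypoxia-inducible genes rose in 29 of 34 cases and fell in 2, the same numbers adjusted over the list alone (camera adjusted p = 9.71e-12, adjusted p = 0.177 with an estimated correlation). NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022), a stress-responsive gene, rose from 670.1 ± 45.8 to 2021 ± 46.3 CPM, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, from 26.1 ± 3.49 to 108 ± 7.05 CPM. Of 30 immediate-early genes 22 rose and 2 fell, in the same numbers adjusted over the list alone (camera adjusted p = 3.67e-08, adjusted p = 0.00844 with an estimated correlation). They included the transcription factors KLF6 (1.28 ± 0.04), FOSL2 (1.45 ± 0.05) and JUN (1.41 ± 0.05).

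Partners of TRIM28 in gene silencing also changed in solvent. Of 22 tested corepressor partners 18 fell and 1 rose, in the same numbers adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.0130 with an estimated correlation). The heterochromatin proteins CBX1 and CBX5 changed by −0.77 ± 0.04 and −0.65 ± 0.04, ATF7IP, which stabilises the histone methyltransferase SETDB1, by −0.85 ± 0.05, and the histone deacetylase HDAC2 by −0.60 ± 0.04. The 3′ untranslated region (UTR) of HDAC2 holds the sequence GACTACAA and those of CBX5, ATF7IP, ACACA, BIRC5 and MCM4 a 7-base part of it. Genes with that sequence in the 3′ UTR had lower counts as a class with TRIM28 siRNA (median log2 fold change −0.23 over 209 genes). Genes of the ZNF family went both ways, with 88 of 357 higher and 103 lower, or 87 and 103 adjusted over the list alone (camera adjusted p = 0.838). ZNF503 rose by 1.05 ± 0.05 and ZNF704 changed by −1.13 ± 0.05. Of 40 interferon-stimulated genes 8 rose and 18 fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.0662), and OAS3, a sensor of double-stranded RNA, fell from 57.4 ± 3.52 to 16.5 ± 0.976 CPM.

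Other large changes in solvent were outside these lists. The carboxypeptidase CPA4 rose from 24.8 ± 2.13 to 131 ± 8.54 CPM and NRP1, a coreceptor for semaphorins and VEGF, from 2.72 ± 0.571 to 18.6 ± 1.83 CPM. PHF6, a chromatin-binding protein, fell from 77.9 ± 2.36 to 15.3 ± 1.09 CPM and NES, which encodes the intermediate filament protein nestin, from 61.0 ± 2.73 to 13.4 ± 1.09 CPM. Of 110 cytosolic ribosomal protein genes 64 rose and 10 fell, or 64 and 11 adjusted over the list alone (camera adjusted p = 6.93e-05, adjusted p = 0.627 with an estimated correlation). RPS27A and RPL6 fell, with log2 fold changes of −1.37 ± 0.04 and −1.15 ± 0.04. Their processed pseudogenes can share reads with them, so these values are uncertain. Mitochondrially encoded genes rose in 11 of 15 cases and fell in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 6.93e-05, adjusted p = 0.283 with an estimated correlation), and MT-RNR1, a mitochondrial ribosomal RNA, rose from 482 ± 36.3 to 1103 ± 83.4 CPM. The mitochondrial share of all counts was 9.36 to 10.3% with control siRNA and solvent and 10.6 to 11.1% with TRIM28 siRNA and solvent. A single siRNA condition against TRIM28 was used, so these counts do not separate the loss of TRIM28 from other actions of the siRNA.

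**Figure D2:**
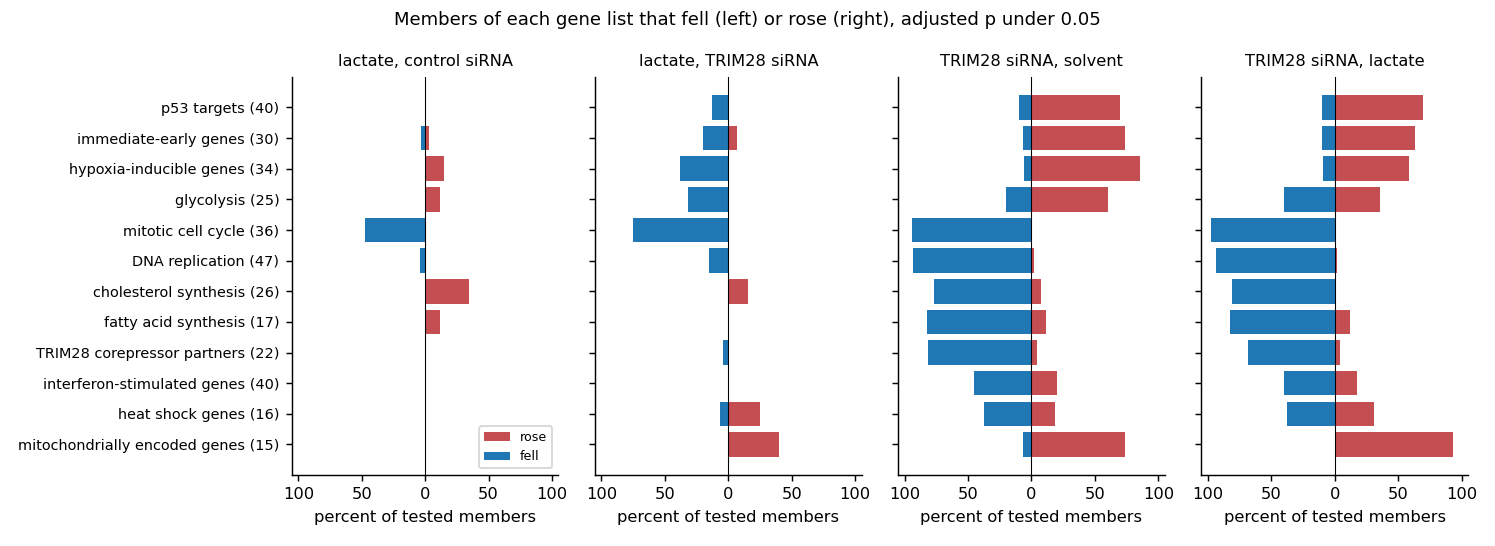
Percent of the tested members (horizontal axis, number in brackets) of 12 gene lists that fell (left, blue) or rose (right, red) at an edgeR adjusted p under 0.05, in 4 comparisons. Of the 36 mitotic genes, 17 fell with lactate in control siRNA cells, 27 with lactate in TRIM28 siRNA cells, 34 with TRIM28 siRNA in solvent and 35 in lactate.

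The same siRNA comparison in lactate gave 9479 changed genes, 4793 higher and 4686 lower, with a median absolute log2 fold change of 0.41. CDKN1A rose from 284 ± 10.1 to 1051 ± 12 CPM (SD, n = 4 each) and GDF15 from 98.9 ± 8.92 to 290.4 ± 13.3 CPM, while MKI67 fell from 619 ± 19.6 to 272 ± 11.8 CPM and SCD from 2453 ± 64.6 to 882 ± 36.5 CPM. Across the 17649 genes the siRNA effects in solvent and in lactate, which share no library, had Pearson r = 0.824 and Spearman rho = 0.825. Genes are not independent replicates, so no p is given. Of 7835 genes changed in both, 3959 rose in both, against 1306 for independent lists of these sizes, 3865 fell in both, against 1269.7, and 11 went opposite ways.

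In lactate 28 of 40 p53 targets rose and 4 fell, in the same numbers adjusted over the list alone (camera adjusted p = 4.72e-11, adjusted p = 0.00124 with an estimated correlation), and 35 of 36 mitotic genes fell, again the same adjusted over the list alone (camera adjusted p = 3.08e-29, adjusted p = 0.00127 with an estimated correlation). CENPF changed by −1.28 ± 0.04 and the helicase subunit MCM7 by −0.91 ± 0.04. Of 17 fatty acid synthesis genes 14 fell and 2 rose, and of 26 cholesterol synthesis genes 21 fell and none rose, with the same numbers adjusted over each list alone (camera adjusted p = 9.81e-09 and 1.17e-10, adjusted p = 0.000949 and 0.0476 with an estimated correlation). FASN changed by −1.02 ± 0.04 and ELOVL1 rose by 1.17 ± 0.04. Immediate-early genes rose in 19 of 30 cases and fell in 3, in the same numbers adjusted over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.0219 with an estimated correlation), with KLF6 at 1.18 ± 0.04 and JUN at 1.34 ± 0.05. Corepressor partners fell in 15 of 22 cases and rose in 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.0200 with an estimated correlation). CBX1 changed by −0.71 ± 0.04, and ATF7IP, whose 3′ UTR holds a 7-base part of GACTACAA, by −0.69 ± 0.05. CPA4, KCNAB3, PHF6, NES and OAS3 changed by 2.29 ± 0.06, 2.32 ± 0.09, −2.19 ± 0.06, −2.32 ± 0.07 and −1.92 ± 0.07. RPS27A, which has processed pseudogenes that can share its reads, changed by −1.28 ± 0.04.

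Fewer hypoxia-inducible genes passed in lactate than in solvent. In lactate 20 of 34 rose and 3 fell, or 20 and 4 adjusted over the list alone (camera adjusted p = 5.51e-05, adjusted p = 0.578 with an estimated correlation). Glycolysis genes went from 15 higher and 5 lower of 25 in solvent (15 and 6 adjusted over the list alone, camera adjusted p = 0.00339, adjusted p = 0.586 with an estimated correlation) to 9 higher and 10 lower in lactate, the same adjusted over the list alone (camera adjusted p = 0.793, median 0.02, mean −0.01). The direction in lactate depended on which control siRNA lactate libraries were used, an alternative added after the data were seen. Without replicates 2 and 4, 12 glycolysis genes were higher and 8 lower (median 0.13). Without replicates 1 and 3, 9 were higher and 10 lower (median −0.15). NDRG1 rose by 1.59 ± 0.06 in solvent and by 0.88 ± 0.06 in lactate. ADM, which encodes the vasodilator adrenomedullin, rose about alike, by 1.12 ± 0.06 in solvent and by 1.09 ± 0.06 in lactate. The difference between the solvent and lactate values is the interaction, tested further on.

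The next comparison asked what lactate changed with TRIM28 present. In control siRNA cells lactate was followed by higher counts of 9 of 26 cholesterol synthesis genes and of a glucose transporter gene and by lower counts of 17 of 36 mitotic genes, and the changes were small. SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42958868), the glucose transporter GLUT1, rose from 255 ± 18.5 to 324 ± 27.9 CPM (SD, n = 4 each), a log2 fold change of 0.35 ± 0.04 (SE, edgeR adjusted p = 3.44e-07). FDFT1 (ENSG00000079459, chromosome 8, 11795573 to 11839304) rose from 339 ± 8.95 to 393 ± 15.6 CPM, and CENPF (ENSG00000117724, chromosome 1, 214603195 to 214664571) fell from 276 ± 6.08 to 233 ± 7.79 CPM. In all, 224 of 17649 genes changed, 140 upward and 84 downward, with a median absolute log2 fold change of 0.23, and 2168 had an unadjusted p under 0.05.

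Of the 26 cholesterol synthesis genes 9 rose and none fell, or 16 and none adjusted over the list alone (camera adjusted p = 1.30e-17, adjusted p = 0.0236 with an estimated correlation). The sterol reductase DHCR7, the mevalonate pathway enzymes MVD and HMGCS1 and FDFT1 rose by 0.20 to 0.22. Of 17 fatty acid synthesis genes FASN (0.18 ± 0.04) and the acetyl-CoA synthetase ACSS2 (0.22 ± 0.05) rose, 2 over all genes tested and 3 adjusted over the list alone (camera adjusted p = 0.00152, adjusted p = 0.0236 with an estimated correlation). Of 36 mitotic genes 17 fell, or 30 adjusted over the list alone, and none rose (camera adjusted p = 9.88e-40, adjusted p = 0.00101 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, changed by −0.23 ± 0.04, the checkpoint kinase BUB1 by −0.24 ± 0.04 and MKI67 by −0.21 ± 0.04. Of 47 DNA replication genes 2 fell, or 11 adjusted over the list alone, RRM2, a subunit of ribonucleotide reductase, by 0.23 ± 0.04 on the log2 scale (camera adjusted p = 6.03e-11, adjusted p = 0.190 with an estimated correlation). The mean log2(CPM + 1) of this list was 5.16 in each of control siRNA lactate replicates 2 and 4. It was 5.38 and 5.25 in replicates 1 and 3, against 5.27 to 5.39 in the solvent libraries.

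Of 34 hypoxia-inducible genes 5 rose with lactate in control siRNA cells, or 8 adjusted over the list alone, and none fell (camera adjusted p = 2.21e-07, adjusted p = 0.239 with an estimated correlation). They were SLC2A1, NDRG1 (0.35 ± 0.06), the histone demethylase KDM4B (0.19 ± 0.05), the growth factor VEGFA (0.20 ± 0.05) and hexokinase HK2 (0.20 ± 0.06). Of 25 glycolysis genes SLC2A1, HK2 and the isomerase GPI (0.19 ± 0.04) rose, 3 over all genes tested and 8 adjusted over the list alone (camera adjusted p = 6.81e-08, adjusted p = 0.190 with an estimated correlation). The mean log2(CPM + 1) of the hypoxia-inducible list was 5.56 and 5.57 in control siRNA lactate replicates 2 and 4, and 5.34 and 5.41 in replicates 1 and 3, within the 5.29 to 5.42 of the solvent libraries. That of glycolysis was 7.39 and 7.37 in replicates 2 and 4, and 7.20 and 7.26 in replicates 1 and 3, against 7.17 to 7.27 in solvent. Without replicates 2 and 4, an alternative added after the data were seen, 1 gene of each list rose and 104 genes were called in all. Without replicates 1 and 3 the numbers were 9, 7 and 149. SLC5A3, a transporter of the osmolyte myo-inositol, rose by 0.25 ± 0.05 as the 1 change among 15 osmotic stress genes, or 3 adjusted over the list alone (camera adjusted p = 0.00497, adjusted p = 0.115 with an estimated correlation). Other rises were those of the calcium-binding protein CALB2 (0.43 ± 0.07), the growth factor PDGFA (0.38 ± 0.09) and ARHGAP22 (0.39 ± 0.10), and other falls those of CDHR5 (−0.57 ± 0.11) and DDIAS (−0.51 ± 0.12). The 7SL RNAs RN7SL1 and RN7SL3, the RNA of the signal recognition particle, changed by −1.14 ± 0.18 and −1.19 ± 0.22. Near-identical copies share reads with them, so their values are uncertain. DESeq2 did not call NDRG1, HK2, GPI, PDGFA, RN7SL1 or RN7SL3, and leaving out a single library could end the call of KDM4B, VEGFA, GPI, HK2, PDGFA, ARHGAP22 or DDIAS. A limma fit of log2 FPKM called 48 genes, and of those named here it kept SLC2A1, CALB2, DHCR7, FDFT1, MVD, CENPF, TOP2A and BUB1 and ended the calls of the others, while the stricter filter ended that of HK2. The count of 224 fell to 113 and 121 without control siRNA lactate replicates 3 and 2, and to 125, 140 and 148 without control siRNA solvent replicates 1, 4 and 2.

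With TRIM28 siRNA, lactate was followed by lower counts of 27 of 36 mitotic, 13 of 34 hypoxia-inducible and 8 of 25 glycolysis genes, and by higher counts of some cholesterol synthesis and mitochondrially encoded genes. CENPF fell from 135 ± 8.43 to 96.2 ± 2.65 CPM (SD, n = 4 each), a log2 fold change of −0.49 ± 0.04 (SE, edgeR adjusted p = 2.82e-13). ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374370) fell from 108 ± 7.05 to 72.0 ± 16.2 CPM and HK2 (ENSG00000159399, chromosome 2, 74834127 to 74893359) from 225 ± 14.9 to 177 ± 19.2 CPM. In all, 705 of 17649 genes changed, 282 upward and 423 downward, with a median absolute log2 fold change of 0.22, and 2888 had an unadjusted p under 0.05.

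Of 36 mitotic genes 27 fell, or 30 adjusted over the list alone, and none rose (camera adjusted p = 3.91e-45, adjusted p = 0.000542 with an estimated correlation). The cytokinesis protein ANLN, TOP2A and MKI67 changed by −0.43 ± 0.04, −0.38 ± 0.04 and −0.34 ± 0.04, and CDC25C, the phosphatase that opens mitosis, by −0.63 ± 0.12. PIF1, a DNA helicase outside the list, changed by −0.70 ± 0.09. Of 47 DNA replication genes 7 fell, the same number adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.597 with an estimated correlation). Among these the ribonucleotide reductase subunits RRM2 and RRM1 changed by −0.43 ± 0.04 and −0.23 ± 0.05, the licensing factor CDT1 by −0.32 ± 0.06 and thymidine kinase TK1 by −0.18 ± 0.04.

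Of 34 hypoxia-inducible genes 13 fell with lactate in TRIM28 siRNA cells, or 17 adjusted over the list alone, and none rose (camera adjusted p = 4.42e-16, adjusted p = 0.171 with an estimated correlation). The collagen prolyl hydroxylase P4HA1 changed by −0.41 ± 0.06 and NDRG1 by −0.36 ± 0.06. Of 25 glycolysis genes 8 fell, or 12 adjusted over the list alone, and none rose (camera adjusted p = 3.42e-11, adjusted p = 0.171 with an estimated correlation). TRIM28 siRNA lactate replicate 2 stood lowest in the mean log2(CPM + 1) of both lists. The hypoxia-inducible list was at 5.62 there, 5.79 to 5.83 in the other lactate libraries and 5.86 to 5.97 in solvent. Glycolysis was at 7.22, 7.33 to 7.34 and 7.40 to 7.48. PFKFB4, which sets fructose 2,6-bisphosphate, the glucose transporter SLC2A3 and the pyruvate dehydrogenase kinase PDK3 changed by −0.34 ± 0.06, −0.39 ± 0.09 and −0.26 ± 0.06. Of 30 immediate-early genes 6 fell and 2 rose, in the same numbers adjusted over the list alone (camera adjusted p = 0.00189, adjusted p = 0.171 with an estimated correlation). JUNB, a subunit of the AP-1 transcription factor, changed by −0.27 ± 0.04, the phosphatase DUSP5 by −0.23 ± 0.04 and the matrix protein CCN1 by −0.40 ± 0.08.

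Of 26 cholesterol synthesis genes 4 rose with lactate in TRIM28 siRNA cells, among them SQLE (0.28 ± 0.04), FDFT1 (0.20 ± 0.04) and DHCR7 (0.18 ± 0.04), or 5 adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.247 with an estimated correlation). Of 15 mitochondrially encoded genes 6 rose, or 9 adjusted over the list alone (camera adjusted p = 8.51e-13, adjusted p = 0.0967 with an estimated correlation). MT-ATP8 rose by 0.65 ± 0.10, though it overlaps another mitochondrial gene and its reads cannot be assigned with certainty, and MT-ND2 by 0.19 ± 0.04. The mitochondrial share of all counts was 10.8 to 12% in these lactate libraries. CYCS, which encodes cytochrome c, rose by 0.29 ± 0.04. Of 17 WNT targets 3 rose, SOX4 (0.23 ± 0.03), MYC (0.16 ± 0.04) and BAMBI (0.45 ± 0.10), and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.233 with an estimated correlation). The chaperone genes DNAJA1 and HSPH1 rose by 0.26 ± 0.04 and 0.25 ± 0.05, while the 16 heat shock genes did not pass as a list (4 rose and 1 fell, or 5 and 2 adjusted over the list alone, camera adjusted p = 0.273). Leaving out a single library could end the call of TK1 or SLC2A3, and the log2 FPKM fit, with 297 calls, ended those of TK1, SLC2A3, NDRG1, PDK3, CCN1, MT-ATP8, MT-ND2 and HSPH1. The count of 705 fell to 404 without TRIM28 siRNA lactate replicate 2, and to 409 and 449 without TRIM28 siRNA solvent replicates 2 and 1.

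**Figure D3:**
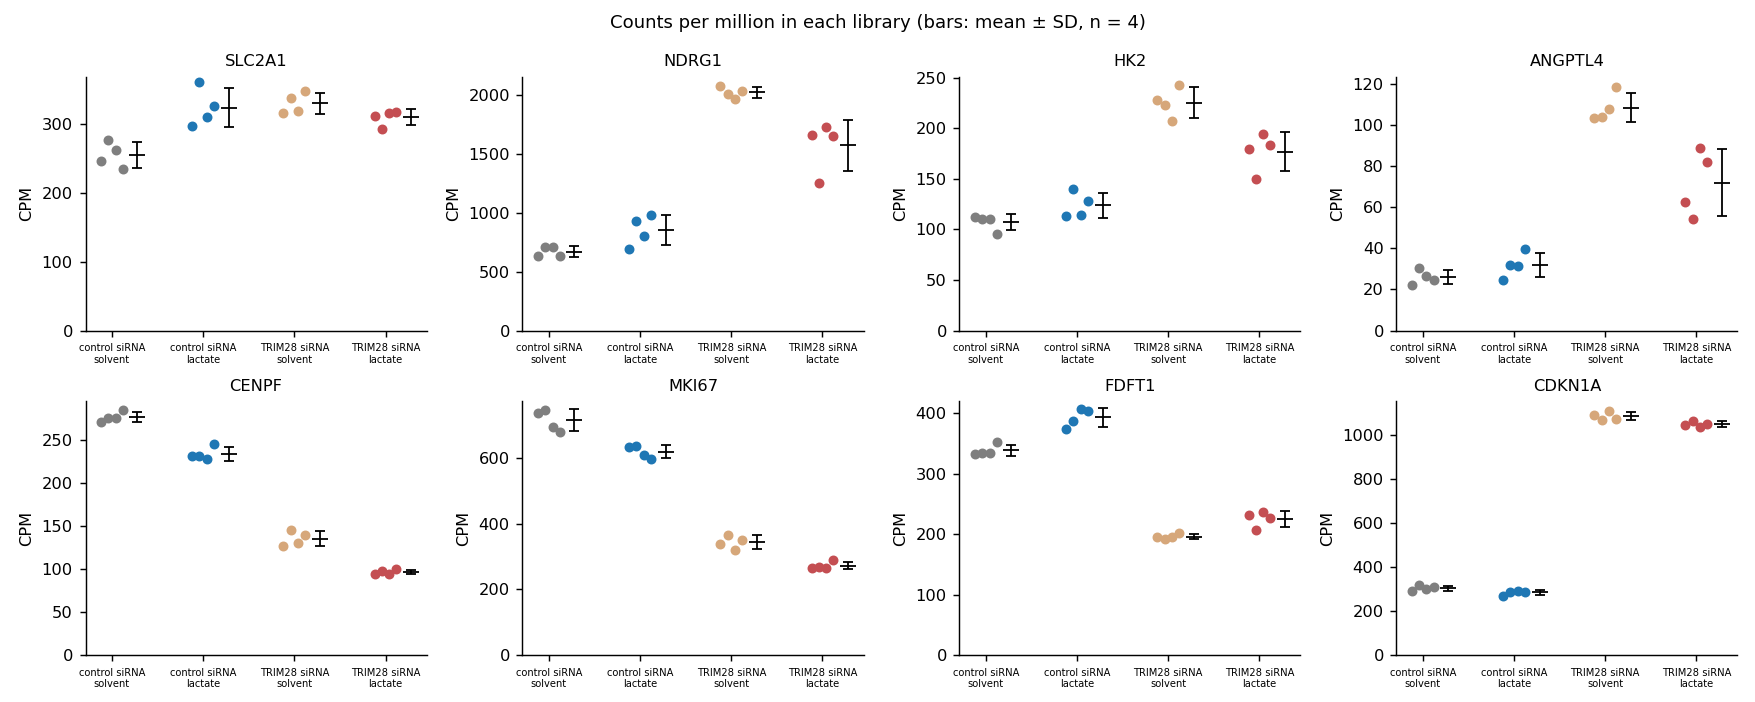
Normalised read counts in CPM (vertical axis) of 8 genes in each of the 16 libraries, by group, with the group mean and SD (n = 4) beside the points. NDRG1 averages 670.1 CPM in control siRNA cells with solvent and 852 with lactate, and 2021 and 1572 CPM in TRIM28 siRNA cells.

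The last comparison asked whether the lactate effect differed between TRIM28 siRNA and control siRNA cells, which is the question the 4 groups were set up for. By edgeR it was called for 9 of 34 hypoxia-inducible and 6 of 25 glycolysis genes, all with a negative interaction. Without control siRNA lactate replicates 2 and 4 the numbers were 4 and 3. NDRG1 rose from 670.1 ± 45.8 to 852 ± 128 CPM with control siRNA and fell from 2021 ± 46.3 to 1572 ± 215 CPM with TRIM28 siRNA (SD, n = 4 each), an interaction of −0.71 ± 0.08 on the log2 scale (SE, edgeR adjusted p = 7.49e-08). HK2 rose from 107 ± 8.04 to 124 ± 12.6 CPM and fell from 225 ± 14.9 to 177 ± 19.2 CPM, an interaction of −0.56 ± 0.08 (edgeR adjusted p = 6.89e-06). In all, 84 genes were called with a different lactate effect, 22 with a positive and 62 with a negative interaction, and 1800 had an unadjusted p under 0.05. By sign, 54 of the 84 were higher with lactate in control siRNA cells and lower in TRIM28 siRNA cells, 19 the reverse and 11 went the same way in both. Only 5 were called as a rise in control siRNA cells and also as a fall in TRIM28 siRNA cells, and 48 of the 84 were called as a fall in TRIM28 siRNA cells.

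Of 34 hypoxia-inducible genes 9 had a negative interaction, or 21 adjusted over the list alone, and none a positive one (camera adjusted p = 4.44e-26, adjusted p = 0.0816 with an estimated correlation). Of 25 glycolysis genes 6 did, or 17 adjusted over the list alone, and none had a positive one (camera adjusted p = 1.13e-21, adjusted p = 0.0816 with an estimated correlation). ANGPTL4 had an interaction of −0.88 ± 0.13, PFKFB4 of −0.51 ± 0.09, SLC2A1 of −0.44 ± 0.06 and GPI of −0.37 ± 0.06. SLC2A1, HK2 and PFKFB4 belong to both lists. Without control siRNA lactate replicates 2 and 4, where both lists stood higher than in the solvent libraries, 4 and 3 genes of these lists had a called negative interaction and 16 genes were called in all, and without replicates 1 and 3 the numbers were 15, 12 and 156. With the lactate labels mixed within each siRNA, the mean log2(CPM + 1) of neither list passed against the largest of all 31 lists (two-sided exact permutation p = 0.162 for hypoxia-inducible genes and 0.130 for glycolysis). For each list by itself the exact permutation p was 0.00571 and 0.00367. The immediate-early list was the 1 of 31 to pass against the largest, with an interaction of its mean of −0.11 (exact permutation p = 0.0273). Of its 30 genes 1 had a called interaction, which was negative, or 6 adjusted over the list alone (camera adjusted p = 9.98e-05, adjusted p = 0.0881 with an estimated correlation). The 3′ UTRs of SLC2A1 and GPI hold a 7-base part of GACTACAA. PDGFA (−0.68 ± 0.11), JUNB (−0.32 ± 0.06), the tight junction gene CLDN4 (−0.27 ± 0.05) and the taurine transporter SLC6A6 (−0.30 ± 0.05) also had negative interactions. The mitotic genes CENPF (−0.25 ± 0.06) and ANLN (−0.24 ± 0.06) fell in both backgrounds and, on the log2 scale, by more with TRIM28 siRNA. They were the 2 of 36 in that list to pass, or 3 adjusted over the list alone (camera adjusted p = 5.08e-07, adjusted p = 0.149 with an estimated correlation).

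Positive interactions were those of MT-ATP8 (0.74 ± 0.13) and MT-ND3 (0.22 ± 0.05), the 2 of 15 mitochondrially encoded genes to pass, or 4 adjusted over the list alone (camera adjusted p = 1.58e-09, adjusted p = 0.116 with an estimated correlation). CYCS followed with 0.30 ± 0.06 and CACYBP, a calcyclin-binding protein, with 0.34 ± 0.07. Of 16 heat shock genes HSPA8 (0.27 ± 0.06), HSPA1B (0.39 ± 0.09) and DNAJA1 (0.24 ± 0.06) passed, 3 over all genes tested and 4 positive and 1 negative adjusted over the list alone (camera adjusted p = 0.000458, adjusted p = 0.173 with an estimated correlation). In control siRNA cells this list passed downward with lactate, with 0 of 16 genes called by edgeR and 4 lower adjusted over the list alone (camera adjusted p = 0.00497, adjusted p = 0.237 with an estimated correlation). Its mean log2(CPM + 1) was 6.71 and 6.73 in control siRNA lactate replicates 2 and 4. In replicates 1 and 3 it was 6.80 and 6.77, against 6.78 to 6.80 in the solvent libraries. HSPA1B has a near-identical copy and its value is uncertain, as are those of RN7SL1 (1.49 ± 0.24) and RN7SL3 (1.57 ± 0.30). The 3′ UTRs of CYCS, HSPA1B and DNAJA1 hold a 7-base part of GACTACAA. The count of 84 fell to 42 without control siRNA lactate replicate 2, to 44 without control siRNA solvent replicate 4, to 45 and 54 without TRIM28 siRNA solvent replicates 2 and 4 and to 50 without TRIM28 siRNA lactate replicate 1, and rose to 138 without control siRNA lactate replicate 1. Leaving out a single library could end the call of CENPF, ANLN, MT-ND3, HSPA8, HSPA1B or DNAJA1, and 3 other groupings that mixed the control siRNA libraries and kept the TRIM28 siRNA groups gave 98 to 228 genes. DESeq2 called 129 genes but not MT-ATP8, HSPA8, RN7SL1 or RN7SL3, and the log2 FPKM fit called 1 gene, SLC6A6.

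**Figure D4:**
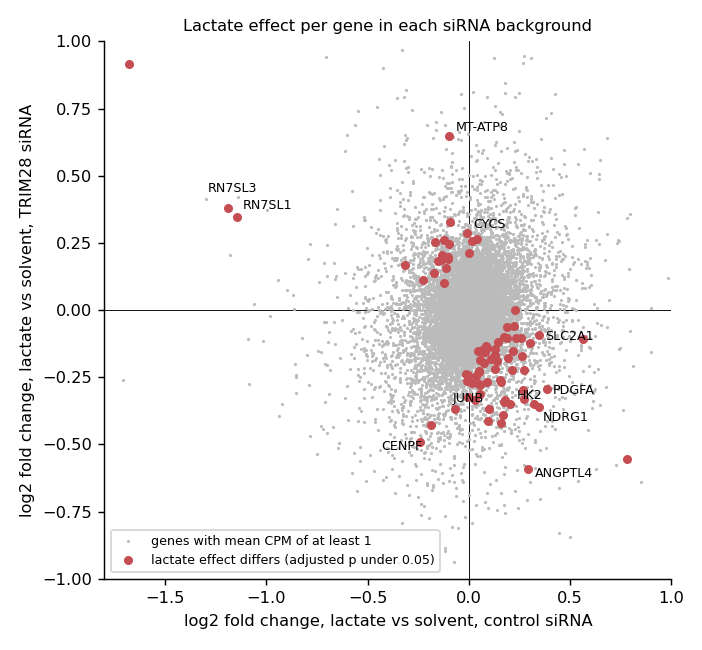
Log2 fold change with lactate in TRIM28 siRNA cells (vertical axis) against that in control siRNA cells (horizontal axis) for each gene with a mean CPM of at least 1 within the axes (grey), and for the 84 genes whose lactate effect differed between them at an edgeR adjusted p under 0.05 (red). Of the 84, 54 lie to the right of 0 and below 0.

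Over all 17649 genes the lactate effects in the 2 siRNA backgrounds, which share no library, had Pearson r = 0.0639 and Spearman rho = 0.127 across genes. Most of these genes were not called, which lowers such a correlation. Of the genes called in control siRNA cells 79.0% had the same sign in TRIM28 siRNA cells. Of those called in TRIM28 siRNA cells 70.9% had the same sign in control siRNA cells. Of the 224 genes changed in control siRNA cells and the 705 changed in TRIM28 siRNA cells, 77 were the same genes. Of these 77, 21 rose in both, against 2.24 for independent lists of these sizes, 50 fell in both, against 2.01, and 6 went opposite ways. Genes changed in both included the mitotic genes CENPF, TOP2A and MKI67, which fell, and the cholesterol synthesis genes FDFT1 and DHCR7, which rose. Of 147 genes called in control siRNA cells and not in TRIM28 siRNA cells, 106 moved in the same direction in both and 16 passed the test of the difference.

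The authors' deposited tables marked 322 genes as changed by lactate in control siRNA cells and 249 in TRIM28 siRNA cells. In the authors' deposited tables every marked gene had an unadjusted p of at most 0.0498 and a fold of at least 1.5, and 1 and 3 of them carried an adjusted p. The same tables gave 186 and 576 genes an adjusted p under 0.05, of which edgeR called 156 and 516. A short deposited sheet held 89 protein-coding genes, all marked in control siRNA cells and none in TRIM28 siRNA cells. The median of their mean counts per library was 8.69, and none carried an adjusted p in the authors' deposited tables. Of the 89, 49 passed the count filter used here, 24 had an unadjusted interaction p under 0.05 and none an edgeR adjusted p under 0.05. The smallest was that of NRIP2, a nuclear receptor interacting protein, which went from 5.31 ± 1.23 to 3.03 ± 0.898 CPM with lactate in control siRNA cells and from 4.07 ± 0.926 to 4.63 ± 0.767 CPM in TRIM28 siRNA cells (SD, n = 4 each). Its interaction was 0.98 ± 0.26 (SE, edgeR adjusted p = 0.0574), that of PRR20G −1.70 ± 0.48 (edgeR adjusted p = 0.0883) and that of the NLR family gene NLRC3 1.06 ± 0.31 (edgeR adjusted p = 0.106). PRR20G belongs to a family of near-identical genes, so its value is uncertain. NRIP2 passed with edgeR adjusted p = 0.0143 without the count filter and 0.0250 with the replicate number as a block, and the range over these and the other alternatives was 0.0143 to 0.310. Leaving out a library gave 0.0187 to 0.163, with values under 0.05 without control siRNA solvent replicate 2 (0.0187), control siRNA lactate replicate 1 (0.0187), TRIM28 siRNA solvent replicate 1 (0.0297) and TRIM28 siRNA lactate replicate 2 (0.0307). NRIP2, PRR20G and NLRC3 were the genes of the sheet called in control siRNA cells by edgeR.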

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

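The tests of library scaling, of chance over all lists, of base composition, of the seed match, of the short sheet with a count filter and of pairs of control siRNA lactate libraries left out were chosen after the result was seen, and the other tests were not. For the count of genes in each comparison the group labels were also mixed. For lactate with control siRNA the real groups gave 224 genes (1 of 35 groupings gave as many) against at most 37 in any other. For lactate with TRIM28 siRNA it was 705 against 7, and for TRIM28 siRNA in solvent and in lactate 9591 and 9479 against 0 in each. These counts argue against a chance division of the libraries but do not exclude it, since 1 of 35 is the smallest share that 35 groupings can give. The other groupings also mix libraries that differ, which widens the spread and lowers their counts. For the interaction, with 84 genes, 4 of 100 groupings gave as many and the highest other gave 228. Only 3 of the other 99 groupings drawn kept the TRIM28 siRNA labels, and each of these gave more genes than the real groups. The 4 of 100 thus reflects how rarely such groupings were drawn, and this test cannot exclude chance for the interaction. The 3 other groupings above 84 gave 98, 175 and 228 genes, and all kept the real lactate and solvent groups of the TRIM28 siRNA libraries while mixing those of the control siRNA libraries. The remaining groupings gave at most 7. Mixing the control siRNA labels takes some or all of the lactate effect of those cells out of the contrast. Lactate effects that both backgrounds share can then count as interactions, so these higher counts do not tell such shared effects from chance. The count of 84 alone does not show that the control siRNA cells responded in their own way.

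Of 34 hypoxia-inducible and 25 glycolysis genes, 53 in all, 9 and 6 had a called interaction (adjusted p = 0.0816 for each list with an estimated correlation), and the median log2 fold change of the 53 was 0.07 with lactate in control siRNA cells, −0.11 in TRIM28 siRNA cells and −0.19 for the interaction. Without control siRNA lactate replicates 2 and 4 the medians in control siRNA cells were 0.0003 for the hypoxia-inducible list and 0.02 for glycolysis. Those of the interaction were then −0.14 and −0.09. Library scaling moves all genes of a library alike, and the members' median lay at −0.18 relative to all genes tested, which argues against it. Camera compares a list with the other genes and had already set both lists lower, so this median is no separate test. A single library is argued against by the median staying at −0.16 or lower whichever was left out. Control siRNA lactate replicates 2 and 4 stand apart, though. Without both, 1 member of each list rose in control siRNA cells and 4 and 3 had a called interaction. Direct seed sites of the siRNA are argued against by the 43 members without one, most of the 53, whose median was −0.19. Genes with GACTACAA in the 3′ UTR had a median interaction of −0.01, so this contrast could show little of a seed effect. Chance over all lists could not be excluded, since 4900 reassignments of the lactate labels gave, against the largest of all 31 lists, a two-sided exact permutation p = 0.162 for the hypoxia-inducible list and 0.130 for glycolysis. For each list by itself the exact permutation p was 0.00571 and 0.00367. The reassignments also mix lactate effects that both siRNA backgrounds share, which can raise the largest t, so this test cannot settle the question. For the mean of the 53 the rise in control siRNA cells had an exact permutation p = 0.171 and the fall in TRIM28 siRNA cells 0.0286, the smallest that 4 against 4 libraries can give, both two-sided. The loss of TRIM28, other actions of the siRNA, culture density, oxygen and medium stay open and were not tested.

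Genes with GACTACAA in the 3′ UTR had lower counts with TRIM28 siRNA, with a median log2 fold change in solvent of −0.23 over 209 genes, 59.8% of which fell, against 0.03 and 28.3% of 10626 genes with neither of its 7-base parts, and GACTACA (z −9.25) and ACTACAA (z −7.52) were the lowest 2 of 15969 sequences of 7 bases. Picked in a random 6380 genes, where both were again the lowest, ACTACAA had z −4.48 in the other 6381 genes (rank 5), and 0 of 104 others of the same bases were as low (lowest z −3.64), which argues against base composition. A candidate explanation is a seed match of the TRIM28 siRNA. In those other genes the 96 with GACTACAA in the 3′ UTR lay −0.12 from the 210 with it in the coding sequence alone (one-sided permutation p = 0.0103, 100000 permutations). Genes with it in the coding sequence alone were low themselves, with a median of −0.10 over all 404 of them, 42.8% of which fell. Lower counts were thus also seen without a 3′ UTR site, and this comparison was not adjusted for 3′ UTR length. The TRIM28 transcript holds GACTACAA once, in the coding part of exon 12, as it does 4.06% of all sequences of 8 bases, but the siRNA sequence is not in the labels, so this stays open. Members without either 7-base part had a median of −0.84 among mitotic genes (33 of 35 with a 3′ UTR tested) and −0.44 among fatty acid synthesis genes (14 of 17). Most members of these lists thus lack such a site, which argues against direct seed sites for the fall of these lists. Among p53 targets the median was 0.67 (35 of 40), but sites that lower counts could not give a rise, so this was no test for that list. Indirect effects of genes lowered in this way stay open for all of these lists.

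The authors' short sheet held genes marked with lactate in control siRNA cells and not in TRIM28 siRNA cells at an unadjusted p. Applied to all genes, a rule of unadjusted p under 0.05 and a fold of 1.5 gave 203 protein-coding genes. Chance could not be excluded, since 8 of 35 groupings of the control siRNA libraries gave as many, with 214 in the highest other. Among genes past the count filter it gave 96, against 79 in the highest other (1 of 35) and a median of 60.5 over the other 34 groupings. The TRIM28 siRNA labels were kept, so this bears only on a lactate effect in control siRNA cells. It argues against chance there without excluding it, since 1 of 35 is the smallest share possible and the count filter was added after the result was seen. The part of the rule on TRIM28 siRNA cells was not tested. The authors' tables marked 91 protein-coding genes in control siRNA cells, and the sheet held 89 of these, so this rule takes more genes than theirs and the test bears on the rule and not on the 89; no biological explanation was tested.

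Of 404 sets of 4 replicates, 24 (5.94%) held a library far from the other 3 by Dixon's measure, and chance gives about 1 in 20. In TRIM28 siRNA lactate replicate 2 the mean log2 CPM of the glycolysis list was 7.22 (7.33 to 7.34 in the others), with NDRG1 at 1253 CPM (1652 to 1725), NES at 12.1 (14.1 to 14.4) and JUN at 94.5 (84.3 to 85.5). TRIM28 siRNA lactate replicate 1 had FASN at 1433 CPM (1583 to 1604) and replicate 4 MKI67 at 289.8 (265 to 269). In control siRNA lactate replicate 1 HSPH1 stood at 136 CPM (116 to 118), IFITM3 at 168 (191 to 194), JUNB at 156 (168 to 170.0) and MT-ATP8 at 54.3 (63.8 to 64.9). Control siRNA lactate replicate 3 had JUN at 32.7 CPM (34.9 to 35.2) and ZNF704 at 131 (119.8 to 121). In TRIM28 siRNA solvent replicate 1 CBX5 stood at 156 CPM (149 in the other 3), GDF15 at 315 (334 to 336), PHLDA2 at 222 (254 to 257) and RPL6 at 407 (438 to 442). CDC25C was at 9.80 CPM (8.20 to 8.47) in TRIM28 siRNA solvent replicate 2, and CBX1 at 140.3 (147 to 148), PDK3 at 42.4 (51.8 to 53.1) and TRIM28 at 75.1 (72.0 to 72.5) in replicate 3. ATF3 was at 9.54 CPM (11.6 to 11.8) in control siRNA solvent replicate 2, and FDFT1 at 352 (333 to 335), FOSL2 at 68.2 (75.9 to 77.2) and HK2 at 95.3 (110.5 to 113) in replicate 4.

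The test of the interaction called a different lactate effect between the siRNA backgrounds in 84 genes and 11 gene lists. Mixing the group labels could not exclude chance for the 84, as given above. The camera adjusted p was 4.44e-26 for hypoxia-inducible genes, 1.13e-21 for glycolysis, 1.58e-09 for mitochondrially encoded genes, 5.08e-07 for mitotic genes, 9.98e-05 for immediate-early genes, 0.000458 for heat shock genes, 0.00804 for cytosolic ribosomal proteins, 0.0312 for cholesterol synthesis and for osmotic stress genes, 0.0340 for epithelial genes and 0.0404 for oxidative phosphorylation. With an estimated correlation none of the 11 passed, and the adjusted p ran from 0.0816 for the first pair to 0.624. Against the largest of all 31 lists over the reassigned lactate labels, the immediate-early list alone passed (two-sided exact permutation p = 0.0273). The named genes with a negative interaction on the log2 scale were ANGPTL4 (−0.88), NDRG1 (−0.71), PDGFA (−0.68), HK2 (−0.56), PFKFB4 (−0.51), SLC2A1 (−0.44), GPI (−0.37), JUNB (−0.32), SLC6A6 (−0.30), CLDN4 (−0.27), CENPF (−0.25) and ANLN (−0.24). Those with a positive one were RN7SL3 (1.57), RN7SL1 (1.49), MT-ATP8 (0.74), HSPA1B (0.39), CACYBP (0.34), CYCS (0.30), HSPA8 (0.27), DNAJA1 (0.24) and MT-ND3 (0.22).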

How the results depend on the processing

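Leaving out libraries for the level of TRIM28 and leaving out pairs of control siRNA lactate libraries were chosen after the result was seen, and all other alternatives here were planned. No count of genes moved by more than 1.5 times with DESeq2's size factors, without a filter, with the stricter filter or, where it was run, with the 2 groups of a comparison alone. DESeq2 gave 129 interaction genes (25 positive and 104 negative, 72 shared with the 84) and stayed within 1.5 times for the other 4 counts, and the cause was not tested. The limma fit of log2 FPKM called 48 genes for lactate with control siRNA (25 higher and 23 lower), 297 with TRIM28 siRNA (93 and 204) and 1 for the interaction, and the cause was not tested. A minimum absolute log2 fold change of 1, which takes a subset of the calls by its construction, left 9, 5 and 4 genes for these, and 1042 and 957 for TRIM28 siRNA in solvent and in lactate.

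With each library left out in turn, a smaller fit by its construction, lactate with control siRNA gave 113 to 223 genes. It gave 113 and 121 without control siRNA lactate replicates 3 and 2, and 125, 148 and 140 without control siRNA solvent replicates 1, 2 and 4. Lactate with TRIM28 siRNA gave 404 to 616 genes, with 404 without TRIM28 siRNA lactate replicate 2 and 449 and 409 without TRIM28 siRNA solvent replicates 1 and 2. The interaction gave 42 to 138, with 44 without control siRNA solvent replicate 4, 138 and 42 without control siRNA lactate replicates 1 and 2, 45 and 54 without TRIM28 siRNA solvent replicates 2 and 4, and 50 without TRIM28 siRNA lactate replicate 1. Without control siRNA lactate replicates 2 and 4 together, lactate with control siRNA gave 104 genes (71 shared with the 224), the interaction 16 and TRIM28 siRNA in lactate 8284. Without replicates 1 and 3 these gave 149 (89 shared), 156 and 8393. Both fits leave out as many libraries, so the number of libraries does not account for 16 against 156 interaction genes. The median lactate effect of the hypoxia-inducible list in control siRNA cells was 0.0003 without replicates 2 and 4. Without replicates 1 and 3 it was 0.16. The cause of the difference was not tested. TRIM28 siRNA in solvent gave 9062 to 9184 genes and in lactate 9011 to 9111. The correlation of the 2 lactate effects across genes (r = 0.0639, jackknife SE 0.0589) ran from 0.0329 to 0.0849 with a library left out, and was 0.00767 without a filter and 0.112 with the stricter one.

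TRIM28 in solvent was 13.6% of control by CPM, 13.4 to 13.9% with a library left out and 13.2% by FPKM, and in lactate 14.4%, 14.1 to 14.6% and 13.9%, where the scaling of FPKM differs by construction. The change of TRIM28 with lactate in control siRNA cells, not called in any fit, turned from 0.02 to −0.00138 without control siRNA lactate replicate 1, with 0.0522 as the highest value over the leave-outs.

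Of 143 values of named genes, DESeq2 kept the side of the threshold of 133 and ended the call of 10, and the log2 FPKM fit kept that of 103 of 148 and ended the call of 45. A minimum absolute log2 fold change of 1 ended 88 of 148, the stricter filter ended 1, and DESeq2's size factors and the 2 groups alone none of 148 and of 123. The interaction of NRIP2 (adjusted p = 0.0574) passed without the filter (0.0143) and with the block (0.0250), the 1 call gained by each, and the cause was not tested. Over the leave-outs 1310 of 1384 values stayed on their side of the threshold, 69 fell below it and 4 rose above it. Of 57 list calls with camera, 15 held with an estimated correlation and 38 with fry.

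With the replicate number as a block the counts were 256, 791, 113, 9631 and 9517 in the order lactate with control siRNA, lactate with TRIM28 siRNA, interaction, and TRIM28 siRNA in solvent and in lactate, and all 57 list calls held. The 24 pairs of libraries with the same number in different groups correlated at −0.0353 to 0.0459, with none above 0.1, so the numbers were not used as pairs. However, 10 of 16 libraries correlated best with one of their own number, more than an even draw over the libraries of other groups would give. Every count was also higher with the block than in the main fit. A weak structure shared by replicate number therefore cannot be excluded.

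Of the 5 comparisons the interaction had the lowest recovery in simulated data at the real depth. There 9% of changes of 0.20 on the log2 scale and 60.5% of changes of 1.5 times were recovered, so genes not called are not shown to lack a difference. All 5 comparisons were simulated with the same depth and spread, so neither makes the interaction the lowest. It combines all 4 groups where each other comparison takes a pair, which widens its error by construction. Whether depth or the spread between replicates sets the level of recovery was not tested.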

Other observations

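No test in this part was added after the result was seen. Imprinted genes went both ways with TRIM28 siRNA in solvent, with 6 of 27 higher and 9 lower, in the same numbers adjusted over the list alone (camera adjusted p = 0.9998). PHLDA2, a growth-limiting gene expressed in placenta, went from 119.6 ± 3.2 to 247 ± 17.0 CPM (SD, n = 4 each), a log2 fold change of 1.05 ± 0.04 (SE), and CDKN1C, which encodes the cell cycle inhibitor p57, from 22.3 ± 0.796 to 44.5 ± 3.04 CPM. Amino acid and integrated stress response genes also split, with 12 of 34 higher and 12 lower, or 13 and 12 adjusted over the list alone (camera adjusted p = 0.871). The serine synthesis enzymes PHGDH and PSAT1 fell by 1.26 ± 0.05 and 1.03 ± 0.06 on the log2 scale, and the stress transcription factor ATF3 rose by 1.38 ± 0.09. IFITM3, an interferon-stimulated gene that restricts virus entry, changed by −0.51 ± 0.05.

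Of 41 oxidative phosphorylation genes 22 rose and 4 fell with TRIM28 siRNA in lactate, the same adjusted over the list alone (camera adjusted p = 0.0120, adjusted p = 0.644 with an estimated correlation), and 17 rose and 5 fell in solvent, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.101). Of 12 replication-dependent histone genes 2 rose and 8 fell in lactate, the same adjusted over the list alone (camera adjusted p = 0.284). Of 8 germline genes 2 rose with TRIM28 siRNA in solvent, the same adjusted over the list alone (camera adjusted p = 0.871). The 6 leukocyte markers tested gave 0 calls in each of the 5 comparisons, also adjusted over the list alone. With lactate in control siRNA cells the corepressor partners passed as a list with 0 of 22 members called by edgeR and 1 lower adjusted over the list alone (camera adjusted p = 0.000541, adjusted p = 0.0947 with an estimated correlation), and the WNT targets with 0 of 17 and 2 higher (camera adjusted p = 0.0131, adjusted p = 0.190 with an estimated correlation). The 7SL RNA RN7SL1 ranged from 115 to 465 CPM over the 16 libraries.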
